A study of Mus musculus with 6 samples.

How the data were processed

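RNA was measured in maxillary first molars of mice at postnatal day 1, in 6 libraries from 3 Ascl5 genotypes with 2 libraries each. Ascl5 encodes a basic helix-loop-helix transcription factor. The libraries were made from total RNA with the SMARTer Stranded RNA-Seq kit, which keeps the strand of each transcript, and sequenced on a NovaSeq, per the labels' protocols. The labels name 1 sequencing batch for all libraries. Per the submitters' processing notes, the authors used the mm10 genome and DESeq2, with no version given. The design text names an Illumina differential expression program. The aligner, the annotation and the strand setting used for counting are not given in the sources used here.

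The authors deposited normalized gene counts, treated here as a signal on a linear scale, in 2 tables of 24972 genes. Each table holds the 2 Ascl5WT/WT libraries with the 2 libraries of 1 mutant genotype, and the tables were normalized separately. Between the tables, the values of Ascl5WT/WT replicate 1 differed by a median ratio of 1.018 and those of replicate 2 by 1.041. Tests were therefore run within a table, and values of the 2 mutant genotypes are set side by side without a test. In the Ascl5Mut/WT table, 11 gene names of the March family were damaged, and these genes were left out where the tables were joined. The 2 libraries of each genotype differ in sex-linked genes, so they are not repeats of 1 sample. The labels do not say how many animals or teeth each sample pooled, and the p-values of single genes measure the spread between these samples.

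Low values clustered at multiples of a step that differed between libraries, from 108.7 to 139.8 normalized counts for what appears to be 1 read. Of the values up to 5 such steps, 83.9% to 93.5% per library lay within 0.1 of a whole number of steps. That share was too low to recover whole reads, so no count model was run, and the planned count tests and the planned test between the 2 mutant genotypes were left out. Dividing each total, which holds only reads assigned to genes, by its step gave an estimated depth of 90476 to 117190 counted reads per library. A gene listed at 0 in a library is therefore compatible with up to 3 reads there, a floor of 326 to 419 normalized counts depending on the library. Depths and floors cover counting error only. Per library, 66.6% to 71.0% of genes were listed at 0, among them genes that every cell uses. Of 81 ribosomal protein genes, 28 were at 0 in at least 1 library. More reads than those counted may have been sequenced. Few reads and a wrong strand in counting were not told apart as causes of these zeros. Genes listed at 0 are given by their values per library.

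Each mutant genotype was compared with Ascl5WT/WT by limma with an intensity trend on log2(normalized count + 1), two-sided, over genes with a mean of at least 10 in the table's 4 libraries. Benjamini-Hochberg adjusted p-values under 0.05 counted as a call. Fold changes are mutant minus Ascl5WT/WT on the log2(value + pseudocount) scale. With a pseudocount of 1, far below the value of 1 read, this overstates the change of genes at 0 in 1 group, and with the pseudocount of 120 used below it understates that of low genes. An exact permutation test of 2 against 2 libraries cannot go below a two-sided p of 0.33 and was not used. Gene lists were tested with camera (limma) with an inter-gene correlation of 0.01 and at least 5 tested members, adjusted over lists. With that preset, camera sets list members against the other genes. Genes rather than samples then act as replicates, and its p-values do not measure the spread between samples. The 49 lists cover tooth cell types, signalling, processes, candidate functions, other cell types that a dissected molar could hold, RNA quality and sex. Members were also adjusted over the list alone. List medians are given too with genes at 0 in both libraries of 1 group set to a floor of 3 estimated reads per library. This design, the lists and the naming rule were set before the data were examined.

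Tested on simulated data with 200 changed genes in 20 simulations, the planned fit recovered 0% of genes changed 4-fold or 16-fold in either comparison. All 200 were drawn from genes with a mean of at least 1000. Settings with a filter at that mean were therefore favoured, and recovery of genes below it was not simulated. With only the pseudocount raised to 120, recovery of 16-fold changes was 0% for Ascl5Mut/Mut and 37.9% for Ascl5Mut/WT, and with only the minimum mean raised to 1000 it was 69.2% and 78.2%. A second setting, called read-scaled here, used a pseudocount of 120, about 1 read, and a minimum mean of 1000. It was chosen after the data were seen, and after the number of calls had been viewed for 15 combinations of pseudocount and filter per comparison. Calls over these combinations ranged from 0 to 24 for Ascl5Mut/Mut and from 0 to 19 for Ascl5Mut/WT, and 5 combinations gave 0 in each. In the simulations for Ascl5Mut/Mut, it recovered 24% of genes changed 4-fold and 81% of those changed 16-fold, with a mean of 7.2 false calls among 112.2. For Ascl5Mut/WT it recovered 35.8% and 88%, with 6 false calls among 129.8. Its adjusted p-values do not account for that choice.

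Genes were named by rule. Always named were Ascl5, Amelx, Ambn, Enam, Mmp20, Dspp, Shh and Cdh1. For each comparison, up to 10 called genes with the largest changes per direction were to be named, among genes with a mean of at least 20 and groups that do not overlap. As fewer than 6 qualified, the 5 genes with the smallest unadjusted p in each direction were added instead, leaving out predicted and unnamed gene models. Up to 4 members were named from each called list and up to 2 from others. After the data were seen, the lists of the second kind were narrowed to tooth and candidate lists. Genes called only under the read-scaled setting, and the pairs of overlapping genes, were chosen after their values were seen.

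Positions come from GENCODE M21 on GRCm38, the assembly that mm10 denotes. Of 24961 gene names shared by both tables, 24434 (97.9%) matched 1 gene there, and 396 more matched a symbol in RefSeq GRCm38.p6. The 2 comparisons share their Ascl5WT/WT libraries, so their agreement was set beside 100 simulations with no effect and the same shared controls. Alternatives to the pseudocount, filter, scaling, trend, replicate block, list correlation and set of libraries were tried. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.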

Results

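Gene expression was profiled in upper first molars of newborn mice to ask how an Ascl5 mutation changes transcript levels when carried on 1 or both alleles. There were 2 libraries each of Ascl5WT/WT, Ascl5Mut/WT and Ascl5Mut/Mut molars at postnatal day 1. Total normalized counts per library ranged from 12304814 to 13118122 over both tables, on an estimated depth of 90476 to 117190 counted reads. Of the genes named in both tables, 3319 were above 0 in all 6 libraries and 11041 were at 0 in all 6. Ascl5 itself (chromosome 1, 136050804 to 136051370, plus strand, GRCm38) was listed at 0 in all 6 libraries, so its level could not be compared.

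In Ascl5Mut/Mut molars, keratins and proteins of keratinizing oral epithelium, extracellular matrix genes, and bone and bone-resorbing cell markers stood higher than in Ascl5WT/WT molars. A list named for the enamel knot, whose genes are not limited to it, stood lower. The 6 gene lists behind this passed camera with its preset correlation and none passed with an estimated correlation (adjusted p = 0.906 to 0.932). That second test rests on the few residual degrees of freedom that 4 libraries leave, so it could hardly call a list. The estimated correlation was 0.52 for keratinized oral epithelium and 0.04 to 0.12 for dental follicle, bone and matrix, but -0.1 for osteoclast and -0.07 for enamel knot. For osteoclast and enamel knot, failing it therefore does not show that correlated genes made a call. For the other 4 lists the estimate lies above the preset 0.01, by far the most for keratinized oral epithelium. There the preset understates the correlation if the estimate holds, and correlated genes may have made the call. Of 10 lists of other cell types that did not pass, 5 had higher sums in both Ascl5Mut/Mut libraries than in either Ascl5WT/WT library. Chance gives this for 16.7% of lists, but these share the same 4 libraries and are not independent. The sums of those 5 were 1.49 to 3.18 times higher, the most for endothelium. Without Ascl5Mut/Mut replicate 2 the endothelium and Schwann cell lists passed as higher and general epithelium as lower, with a median of -1.29 (camera adjusted p = 0.0133 for each). With all libraries and an estimated correlation their adjusted p was 0.953 to 0.955. Krt4, a keratin of mucosal epithelium, had 5922 and 38281 normalized counts in the 2 Ascl5Mut/Mut libraries against 109 and 0 in Ascl5WT/WT. Ctsk, the collagen-degrading protease of osteoclasts, had 11106 and 7277 against 109 and 120, about 1 estimated read in each Ascl5WT/WT library. Shh, the hedgehog ligand made by the enamel knot and dental epithelium, had 2146 and 1340 in Ascl5WT/WT and was listed at 0 in both Ascl5Mut/Mut libraries. Its exons overlap the antisense gene 9530036O11Rik by 446 bases. Values of genes with such an overlap, among them Gpr39, Dlx1, Copg2 and Gm11532 below, may belong to the gene opposite. This is taken up with the strand tests at the end. Dlx1, a homeobox gene of the jaw mesenchyme, had 1452 ± 1267 against 50280 ± 4322 (SD, n = 2 each).

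No single gene passed the planned test for Ascl5Mut/Mut. limma called 0 of 12731 genes, with 1280 at an unadjusted p under 0.05 and a smallest adjusted p of 0.163. In the simulations this fit recovered 0% of changed genes, all drawn from genes with a mean of at least 1000. Without Ascl5WT/WT replicate 1, Ascl5WT/WT replicate 2 or Ascl5Mut/Mut replicate 2 it called 1448, 1595 and 1507 genes, of which at least 99.2% were at 0 in both libraries of the complete group. Under the read-scaled setting, chosen after the data were seen, limma called 20 of 2336 genes, 13 higher and 7 lower, with 261 at an unadjusted p under 0.05. That count fell to 7 without Ascl5WT/WT replicate 1 and to 0 without Ascl5Mut/Mut replicate 1 or replicate 2. It was 33 without Ascl5WT/WT replicate 2.

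Genes that fell under that setting included Gpr39, Dlx1, Tdrd1, Afap1l2 and Numb, and each of these calls was lost without either Ascl5Mut/Mut library. Those of Tdrd1, Afap1l2, Numb and the model Gm11532 below were also lost without Ascl5WT/WT replicate 1. Those of Tdrd1 and Afap1l2 were lost without Ascl5WT/WT replicate 2 too. Gpr39, a zinc-sensing receptor (chromosome 1, 125676995 to 125873862), fell by 4.58 on the log2 scale (SE 0.36, limma adjusted p = 0.000383). It had 58793 and 58649 in Ascl5WT/WT against 2100 and 2599. Its exons overlap those of Lypd1 on the opposite strand by 1202 bases, so the fall may be that of Lypd1. Dlx1 (chromosome 2, 71528113 to 71533981) fell by 5.28 (SE 0.57, limma adjusted p = 0.00405), and it overlaps the antisense gene Dlx1as by 335 bases. Tdrd1 fell by 5.47 (SE 0.98, limma adjusted p = 0.0356), with values of 21355 and 16039 in Ascl5WT/WT against 0 and 1345. Afap1l2 fell by 3.76 (limma adjusted p = 0.0271), and Numb, an inhibitor of Notch signalling, fell by 2.88 (limma adjusted p = 0.0403). The unnamed model Gm11532, the feature with the highest value in both Ascl5WT/WT libraries, had 869884 and 389895 there against 2113 and 29497 in Ascl5Mut/Mut. It overlaps the enamel epithelium gene Sp6 on the opposite strand by 3329 bases, and it fell by 6.16 (SE 0.91, limma adjusted p = 0.0162). Sp6 itself had 1525 and 0 in Ascl5WT/WT and was listed at 0 in both Ascl5Mut/Mut libraries. The reads counted for Gm11532, and their fall, may be those of Sp6.

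Genes that rose under the same setting, again with no call left without either Ascl5Mut/Mut library, included a pair of keratins that assemble together in mucosal epithelium. The calls of Krt13, Rptn, Postn, Igfbp5 and Copg2 given below were also lost without Ascl5WT/WT replicate 1. That of Copg2 was lost without Ascl5WT/WT replicate 2 too. Krt4 rose by 6.52 on the log2 scale (SE 0.93, limma adjusted p = 0.0151). Krt13 rose too (limma adjusted p = 0.0271), with 5344 and 38097 against 0 and 306. Rptn, a protein of the cornified envelope, was listed at 0 in both Ascl5WT/WT libraries and had 3948 and 17423 in Ascl5Mut/Mut (limma adjusted p = 0.0403). Ctsk rose by 5.28 (SE 0.74, limma adjusted p = 0.0151). Postn, a matrix protein of the dental follicle and periodontal ligament, rose from 2215 ± 270 to 13791 ± 3300 (SD, n = 2 each, limma adjusted p = 0.0356). Igfbp5, a binding protein for insulin-like growth factors, rose from 9249 ± 2295 to 41234 ± 3630 (SD, n = 2 each, limma adjusted p = 0.0218). Perm1 rose by 2.62 (SE 0.37, limma adjusted p = 0.0151). Copg2 rose by 1.49 (SE 0.26, limma adjusted p = 0.0337) and overlaps the imprinted gene Mest on the opposite strand by 912 bases. The rise may be that of Mest.

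By camera, 6 of 43 lists passed in Ascl5Mut/Mut, 5 higher and 1 lower. The keratinized oral epithelium list rose, with a median log2 fold change of 5.30 and all 17 tested members above 0 (camera adjusted p = 8.17e-08). The adjusted p was 0.906 with an estimated correlation. With genes at 0 set to the floor the median was 2.95. No member passed over all genes in the planned fit, and 4 passed when adjusted over the list alone. Krt76, Sprr3, Krtdap and Krt16 were listed at 0 in both Ascl5WT/WT libraries, and Krt76 had 2761 and 20277 in Ascl5Mut/Mut. The sum over the list was 18027 and 123609 in the 2 Ascl5Mut/Mut libraries, so replicate 2 held most of it. Without Ascl5Mut/Mut replicate 1 the median was 9.67.

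The fibrillar collagen and matrix list rose too, with a median of 1.48 and 19 of 21 members above 0 (camera adjusted p = 1.35e-07). The adjusted p was 0.906 with an estimated correlation. The median was 1.46 with genes at the floor, and 1 member passed when adjusted over the list alone. Values of Col3a1, a fibrillar collagen of soft connective tissue, were 7524 ± 2395 against 2515 ± 165, and those of Sparc, a collagen-binding matrix protein, were 8092 ± 1425 against 1851 ± 908 (SD, n = 2 each). Tnc had 5688 ± 266 against 332 ± 301 (SD, n = 2 each). Without Ascl5Mut/Mut replicate 1 this call was lost (camera adjusted p = 0.0916).

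Osteoclast genes rose as a list (median 5.16, 8 of 9 members above 0, camera adjusted p = 0.00641), as did osteoblast and bone matrix genes (median 4.36, 11 of 15, camera adjusted p = 0.0245) and dental follicle genes (median 1.28, 12 of 14, camera adjusted p = 0.0175). With an estimated correlation the adjusted p was 0.906, 0.932 and 0.906. With genes at the floor these medians were 0.97, 0.39 and 0.07. Adjusted over the list alone, 2 osteoclast genes were higher, 0 bone genes passed, and 3 dental follicle genes were higher with 1 lower. Mmp9, an osteoclast protease, had 4815 and 1661 against 109 and 0. Ibsp, bone sialoprotein, had 20547 ± 1817 against 2909 ± 3648 (SD, n = 2 each). Phex and Dmp1, regulators of mineralization, were listed at 0 in Ascl5WT/WT and had 1551 and 945, and 692 and 551, in Ascl5Mut/Mut. Leaving out any 1 of the 4 libraries ended the osteoclast call (camera adjusted p = 0.0567 to 0.176) and the dental follicle call (0.0761 to 0.569), whose median was 2.46 without Ascl5WT/WT replicate 2. The bone call was lost without Ascl5Mut/Mut replicate 1, with a median of 1.61 (camera adjusted p = 0.569), and its median was 6.44 without replicate 2.

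The list named for the enamel knot, a signalling centre that directs cusp formation, fell with a median of -3.92 and 11 of 14 members below 0 (camera adjusted p = 0.00641). Members such as Shh are made by dental epithelium too, so the fall cannot be placed in the enamel knot. The adjusted p was 0.906 with an estimated correlation. With genes at 0 set to the floor its median was 0. Adjusted over the list alone, 2 members were lower. Besides Shh, the list holds Sostdc1, a secreted BMP and Wnt antagonist, at 1413 and 1684 in Ascl5WT/WT, and Bmp7 at 881 and 119. Sostdc1 and Bmp7 were listed at 0 in both Ascl5Mut/Mut libraries. The call was lost without Ascl5Mut/Mut replicate 1 (camera adjusted p = 0.129).

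Under the read-scaled setting 3 of these 6 lists had enough tested members and all 3 were called in Ascl5Mut/Mut, and none passed with an estimated correlation (adjusted p = 0.407 to 0.548). Keratinized oral epithelium (median 3.79, camera adjusted p = 7.41e-06) was called without any 1 library too (1.98e-07 to 7.3e-05), with a median of 2.21 without Ascl5Mut/Mut replicate 2. Fibrillar collagen and matrix (median 1.36, 3.43e-09) was also called without any 1 library (7.45e-11 to 4.64e-05). Dental follicle (median 1.20, 0.00266) was lost without Ascl5Mut/Mut replicate 1 (0.0556) and called without each of the others (0.00257 to 0.0067).

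**Figure D1:**
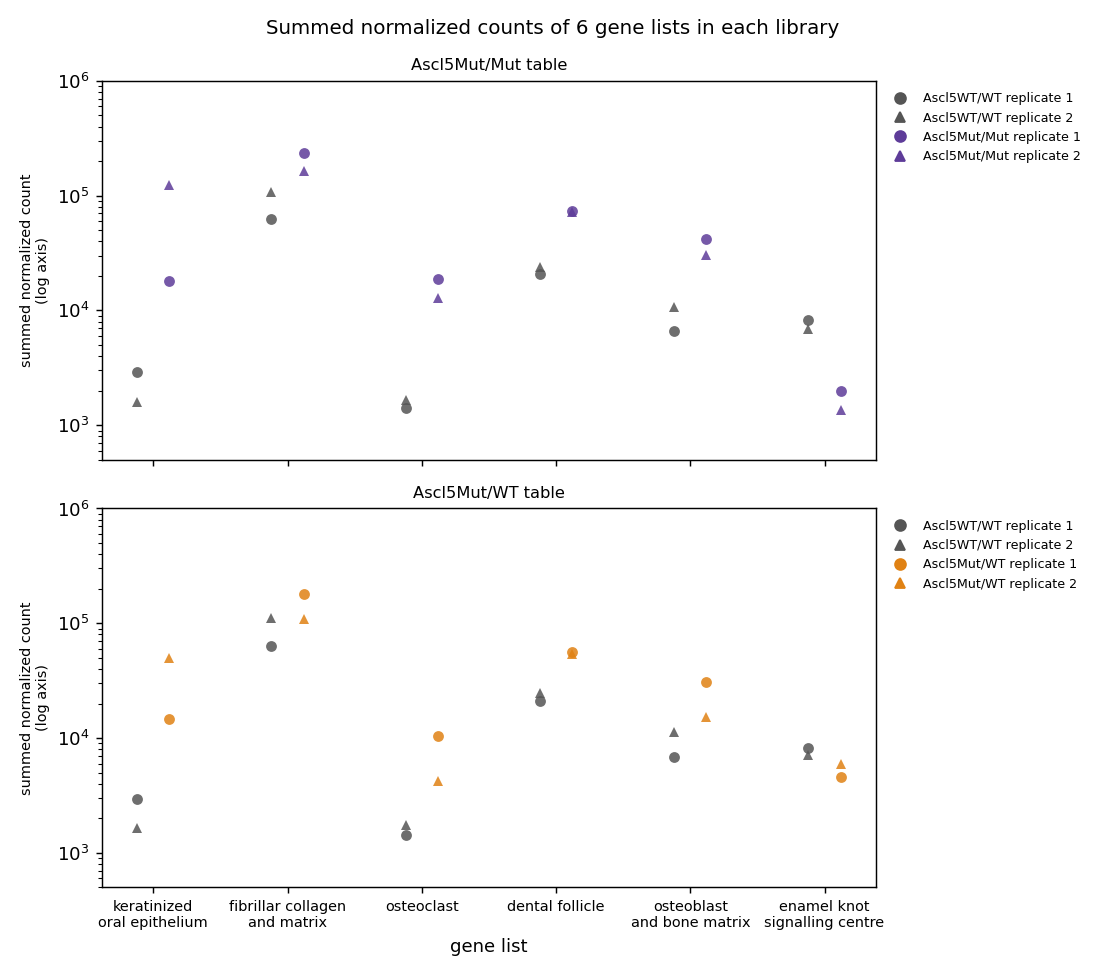
Summed normalized counts per library (log axis) for the 6 lists called in Ascl5Mut/Mut, with 1 panel per deposited table. Each point is 1 library, a circle for replicate 1 and a triangle for replicate 2. In the upper panel keratinized oral epithelium stood at 18027 and 123609 in Ascl5Mut/Mut against 2902 and 1602 in Ascl5WT/WT, and the enamel knot list at 1996 and 1358 against 8272 and 6957.

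Enamel matrix genes were close to the floor in this comparison. Amelx and Mmp20 were listed at 0 in all 4 libraries, Ambn had 140 in 1 Ascl5Mut/Mut library, and Enam had 109 in 1 Ascl5WT/WT library. Dspp, the dentin matrix gene of odontoblasts, had 327 in Ascl5WT/WT replicate 1 and was listed at 0 in the other libraries. The enamel matrix and ameloblast list did not pass (camera adjusted p = 0.919), nor did odontoblast and dentin (0.207) or dental papilla mesenchyme (0.928), the list that holds Dlx1. Trp63, a regulator of epithelial stem cells, had 3439 ± 3380 against 17445 ± 5216 (SD, n = 2 each) without passing the planned or the read-scaled fit, and the list of dental epithelial transcription factors did not pass either (camera adjusted p = 0.302). Cdh1, the epithelial cadherin, had 1025 ± 1053 against 1107 ± 641 (SD, n = 2 each). Among the genes with the smallest unadjusted p, Omg, Dst, Masp2, Hsp90ab1 and Slc24a5 passed neither the planned nor the read-scaled fit (limma adjusted p = 0.308 for each in the planned fit). Hsp90ab1, a cytosolic chaperone, had 12092 ± 624 against 38723 ± 10927 (SD, n = 2 each).

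In Ascl5Mut/WT molars, Dspp, mucosal keratins and Igfbp5 stood higher than in Ascl5WT/WT and Dlx1 and Gpr39 stood lower. Dspp had 14045 and 8122 normalized counts in the 2 Ascl5Mut/WT libraries against 336 and 0 in Ascl5WT/WT. Krt4 had 8146 and 15031 against 111 and 0. Shh was 1334 ± 281 against 1771 ± 553 (SD, n = 2 each, limma adjusted p = 0.75), a difference within the spread.

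limma called 0 of 12644 genes for Ascl5Mut/WT, with 1055 at an unadjusted p under 0.05 and a smallest adjusted p of 0.559. Leaving out 1 library gave 1179 and 1257 calls without Ascl5WT/WT replicate 1 and 2, and 1441 and 1337 without Ascl5Mut/WT replicate 1 and 2, at least 99.2% of them genes at 0 in both libraries of the complete group. The read-scaled setting called 13 of 2370 genes, 8 higher and 5 lower, with 207 at an unadjusted p under 0.05. That count was 0 without Ascl5Mut/WT replicate 1 or replicate 2. It was 20 without Ascl5WT/WT replicate 1 and 34 without replicate 2. Under that setting Dspp (chromosome 5, 104170712 to 104180127) rose by 5.53 (SE 0.76, limma adjusted p = 0.000399) and Krt4 by 6.07 (SE 0.79, limma adjusted p = 0.000261). Krt13 rose by 5.16 (SE 0.90, limma adjusted p = 0.0062). Igfbp5 rose from 9543 ± 2515 to 35567 ± 238 (SD, n = 2 each, limma adjusted p = 0.0068), and Mas1, a receptor for angiotensin fragments, from 3402 ± 867 to 16258 ± 48 (SD, n = 2 each, limma adjusted p = 0.0072). Perm1 rose by 2.21 (SE 0.40, limma adjusted p = 0.0068). Dlx1 fell from 51851 ± 5282 to 3361 ± 1834 (SD, n = 2 each, limma adjusted p = 1.41e-05), and Gpr39 fell by 3.98 (SE 0.50, limma adjusted p = 0.000249). Tdrd1 fell by 2.05, Afap1l2 fell by 1.86 and Wdr76 fell by 2.40 (limma adjusted p = 0.00922, 0.024 and 0.0297). The Wdr76 call was also lost without either Ascl5WT/WT library, that of Tdrd1 without Ascl5WT/WT replicate 1 and that of Afap1l2 without Ascl5WT/WT replicate 2.

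**Figure D2:**
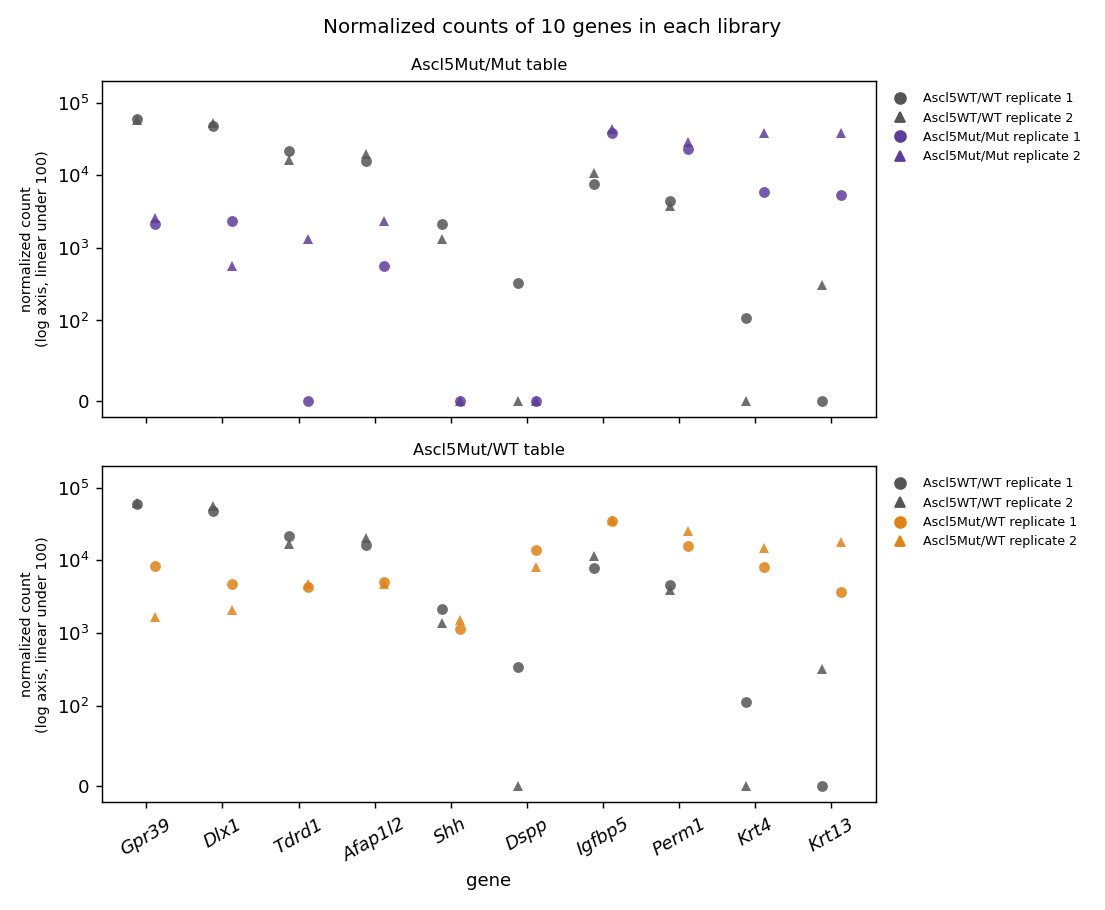
Normalized counts of 10 genes per library, on an axis that is logarithmic above 100 and linear below, with 1 panel per deposited table. Each point is 1 library, a circle for replicate 1 and a triangle for replicate 2. Dspp stood at 14045 and 8122 in Ascl5Mut/WT against 336 and 0 in Ascl5WT/WT, and Shh was listed at 0 in both Ascl5Mut/Mut libraries.

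Of 43 lists, 2 passed in Ascl5Mut/WT. Keratinized oral epithelium rose (median 4.55, 12 of 14 members above 0, camera adjusted p = 0.000609), with a median of 0.26 when genes at 0 were set to the floor. Fibrillar collagen and matrix rose (median 1.00, 17 of 21 members above 0, camera adjusted p = 0.0393), with a median of 0.99 at the floor. The estimated correlation was 0.37 and 0.07, above the preset 0.01, and with it the camera adjusted p was 0.953 for both. In both lists 0 members passed when adjusted over the list alone. Leaving out any 1 of the 4 libraries ended the collagen call (camera adjusted p = 0.0605 to 0.879), and its median was 0.49 without Ascl5WT/WT replicate 1. The keratinized epithelium call was lost without Ascl5WT/WT replicate 1 (0.0925), Ascl5WT/WT replicate 2 (0.0515) or Ascl5Mut/WT replicate 2 (0.446). Its median was 0.98 without Ascl5Mut/WT replicate 2 and 8.97 without replicate 1. Under the read-scaled setting it was called (median 3.36, camera adjusted p = 1.99e-05), and again without any 1 library (2.39e-07 to 0.00159), but not with an estimated correlation (0.543). Its median there was 1.96 without Ascl5Mut/WT replicate 2 and 5.08 without replicate 1. The collagen list was called under that setting (median 0.97, camera adjusted p = 0.00157) and lost with an estimated correlation (0.543), without Ascl5WT/WT replicate 1 (0.195, median 0.41) or without Ascl5Mut/WT replicate 1 (0.0728). Col3a1 had 5148 ± 399 against 2571 ± 210, and Postn 5269 ± 1859 against 2273 ± 241 (SD, n = 2 each). The lists for osteoblast and bone matrix (camera adjusted p = 0.0676), osteoclast (0.0778), dental follicle (0.0778), odontoblast and dentin (0.12), enamel matrix and ameloblast (0.603) and enamel knot signalling centre (0.718) did not pass the planned test. Other settings called some of them. Under the read-scaled setting odontoblast and dentin rose (median 1.01 over 5 tested members, camera adjusted p = 0.000524), and the adjusted p was 0.543 with an estimated correlation. That call was lost without Ascl5Mut/WT replicate 1 (camera adjusted p = 0.0954, median 0.68). Its median was 1.83 without Ascl5Mut/WT replicate 2, and 0.56 and 1.53 without Ascl5WT/WT replicate 1 and 2. Dspp is 1 of the 5. The osteoblast and bone matrix list passed with a pseudocount of 8 (camera adjusted p = 0.0475) or 120 (0.00847) or quantile normalization (0.0397), osteoclast with a pseudocount of 120 (0.0113), and dental follicle with a filter of 50 (0.0385). With an estimated correlation the planned adjusted p of these 3 lists was 0.953.

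Enamel matrix genes were low in both groups. Ambn had 383 and 136 in Ascl5Mut/WT and was listed at 0 in both Ascl5WT/WT libraries. Enam had 252 and 809 against 113 and 0. Amelx and Mmp20 had 127 and 253 in Ascl5Mut/WT replicate 1 and were listed at 0 elsewhere. Cdh1 had 1217 ± 1542 against 1147 ± 680 (SD, n = 2 each). Copg2, Adamtsl4 and Aldh1b1 had unadjusted p-values among the smallest. None of the 3 passed the planned or the read-scaled fit. Aldh1b1, a mitochondrial aldehyde dehydrogenase, had 204 ± 110 against 4214 ± 1035 (SD, n = 2 each).

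The 2 comparisons were then set beside each other. Across the 11438 genes tested in both, the log2 fold changes had a covariance of 7.90, against a mean of 5.85 and a highest value of 6.18 in 100 simulations with no effect and the same shared controls. The difference was 2.05. The correlation across genes, which are not independent replicates, was 0.604 against a simulated mean of 0.537, and 71.3% of genes had the same sign against 68%. The 2 control libraries were too few to give each comparison its own pair, so part of the excess may come from them. Simulated genes varied independently, with a spread set by expression level alone and taken from the Ascl5Mut/Mut comparison. Real genes can vary together, so the simulated ranges, here and for the shared genes below, may be too narrow. The planned fit called 0 genes in either comparison and so none in both. Under the read-scaled setting, over 2029 genes tested in both, 6 genes were called higher in both and 4 lower in both. In 100 simulations with no effect and the same shared controls, as many top genes in each comparison shared a mean of 2.1 higher and 0.44 lower, and at most 5 and 2. The shared genes were Igfbp5, Krt4, Krt13, Perm1 and the unnamed models Gm10389 and 5031410I06Rik, higher, and Afap1l2, Dlx1, Gpr39 and Tdrd1, lower. Differences between the 2 mutant genotypes, such as those at Dspp and Shh, were not tested.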

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

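The settings with a pseudocount of 120 or a minimum mean of 1000, and all alternatives to the read-scaled setting, were chosen after the data were seen. The planned count of 0 called genes for Ascl5Mut/Mut was unchanged with a pseudocount of 0.25 or 8, a filter of 50, upper-quartile or quantile scaling, no trend and a robust fit. Removing the filter changed no tested gene. The count became 1 with a pseudocount of 120, 4 with a filter of 1000, 20 with both, and 36 with both and a replicate block. For Ascl5Mut/WT the planned settings also gave 0, and these 4 gave 12, 8, 13 and 37. Leaving out 1 library gave 0 to 1595 calls for Ascl5Mut/Mut and 1179 to 1441 for Ascl5Mut/WT. Where it gave calls, at least 99.2% were genes at 0 in both libraries of the complete group, so with no spread there. The lone library of the other group is assumed to vary like the rest. The read-scaled counts ranged over left-out libraries from 0 to 33 and from 0 to 34. Under quantile normalization the Ascl5Mut/Mut count was 40, with 24 higher and 16 lower, and under upper-quartile scaling 23, with 13 higher and 10 lower. All 20 genes remained in both. In the planned Ascl5Mut/Mut fit these scalings moved the median of all genes from -0.008 to -0.129 and -0.1. The cause of the other changes was not tested.

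The replicate numbers are shared by all genotypes, but no label says that they mark a litter or day, and deviations of same-numbered libraries correlated at -0.04 to 0. With the replicate block the planned fit called 12 genes for Ascl5Mut/Mut and 0 for Ascl5Mut/WT, and the read-scaled fit 36 and 37, which kept all 20 and 13 genes called without it. Some settings that keep all libraries were checked gene by gene. Of these, only those with the block called Hsp90ab1, Trp63, Tnc, Ibsp, Krt76 and, in the planned fit, Masp2 for Ascl5Mut/Mut. For Ascl5Mut/WT only they called Adamtsl4 and Aldh1b1. Further calls under read-scaled upper-quartile or quantile scaling, and over the 15 combinations of pseudocount and filter, were only counted and may include these genes. The block also called the osteoblast and bone matrix list for Ascl5Mut/WT in the planned fit. The block coincides with the split in sex-linked genes.

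The number of called lists in Ascl5Mut/Mut was 0 with an estimated correlation in both the planned and read-scaled settings, and 1 to 9 without 1 library. A test of depth, written before its result was seen, thinned reads to the shallowest library. For lists higher in the mutants it decides nothing, as Ascl5WT/WT was deeper. The enamel knot list, added to it afterwards, passed in each of 20 thinnings. In Ascl5Mut/WT it was 0 with an estimated correlation in both, 1 with a pseudocount of 0.25, 5 with quantile normalization, 6 with a pseudocount of 120, 4 with the read-scaled setting and replicate block, and 0 to 2 without 1 library. The correlation between comparisons was 0.602 with a pseudocount of 8, 0.615 with a filter of 50 and 0.735 read-scaled. In each of these, 0 of 100 simulations reached the observed covariance, though simulated genes varied independently and real genes may not.

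Among named genes, no direction turned under the settings that keep all libraries and were checked gene by gene. Without 1 library the log2 fold change of Cdh1 ranged from -1.85 to 0.81 in Ascl5Mut/Mut and from -3.03 to 1.15 in Ascl5Mut/WT, and that of Cdc25b from -10 to 0.28 in Ascl5Mut/Mut. Ranges that reached 0 were 0 to 7.14 for Ambn, -6.78 to 0 for Enam and -8.36 to 0 for Dspp in Ascl5Mut/Mut, and 0 to 7.0 for Amelx and 0 to 7.99 for Mmp20 in Ascl5Mut/WT, each resting on 1 library above 0. The planned tests with edgeR and DESeq2, and the whole comparison of Ascl5Mut/Mut with Ascl5Mut/WT, were not run, since whole reads were not recovered. Ascl5, at 0 throughout, gave no value under any setting. The number of counted reads limits what can be seen: a gene listed at 0 may hold up to 3 reads.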

Other observations

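Of the tests below, those on antisense RNA genes, on Tsix and Xist, on the lists of other cell types, on depth, on enamel matrix genes and on Dspp per bone value were chosen after the values were seen. Some ribosomal protein genes and the features opposite them had also been seen before that test was written.

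Outside the tooth lists, several sets of cell type markers varied widely between libraries of 1 genotype. Skeletal muscle genes summed to 259383 and 10668 normalized counts in the 2 Ascl5Mut/Mut libraries against 8925 and 42548 in Ascl5WT/WT, and the list did not pass (camera adjusted p = 0.242). Erythroid genes summed to 1847 and 26530 in Ascl5WT/WT and to 5503 and 3938 in Ascl5Mut/Mut (camera adjusted p = 0.919). The median of the muscle list was 6.43 without Ascl5Mut/Mut replicate 2 and 5.41 without Ascl5WT/WT replicate 2. It was -1.69 without Ascl5Mut/Mut replicate 1 and -0.94 without Ascl5WT/WT replicate 1. The muscle list passed with a pseudocount of 120 (camera adjusted p = 0.0358). With an estimated correlation its planned adjusted p was 0.955. Ribosomal protein genes did not pass the planned test in either comparison (camera adjusted p = 0.143 and 0.0778), with medians of -0.34 in both. Their Ascl5Mut/WT medians without 1 library ranged from -0.62 without Ascl5WT/WT replicate 1 to 0 without Ascl5WT/WT replicate 2. For Ascl5Mut/Mut they passed as lower under the read-scaled setting (median -0.35 over 38 members, camera adjusted p = 0.0234), with upper-quartile scaling (0.0443) and with a filter of 1000 (0.0202). With an estimated correlation the read-scaled adjusted p was 0.712. It was 0.555 without Ascl5WT/WT replicate 2 and 0.262 without Ascl5Mut/Mut replicate 1, with medians of -0.07 and -0.2, and the median was -0.66 without Ascl5WT/WT replicate 1. The planned test passed without Ascl5Mut/Mut replicate 2 (0.0383) and, for Ascl5Mut/WT, without Ascl5Mut/WT replicate 1 (0.0115) or with quantile normalization (0.0411). Genes of immediate early response and dissection stress summed to 10176 and 11769 in Ascl5Mut/Mut against 8821 and 5339 in Ascl5WT/WT. Nuclear oxidative phosphorylation genes summed to 15758 and 17532 against 18338 and 19059. Neither list passed (camera adjusted p = 0.331 and 0.762). For Ascl5Mut/WT the immediate early sums overlapped between groups. Oxidative phosphorylation genes summed to 13528 and 16218 against 18511 and 19842, and replication-dependent histone genes to 15628 and 14370 against 17082 and 26513. Neither of these 2 lists passed there (camera adjusted p = 0.718 and 0.89). The cell cycle list did not pass for Ascl5Mut/Mut or Ascl5Mut/WT (camera adjusted p = 0.158 and 0.0688), though for Ascl5Mut/WT it passed as lower with a pseudocount of 120 (0.0257) or quantile normalization (0.0411) and not with an estimated correlation (0.953). The median, the mean and the test differed in sign in 10 of 43 lists for Ascl5Mut/Mut and 8 of 43 for Ascl5Mut/WT, none of them called.

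Replicate number coincided with sex-linked genes. Eif2s3y, on the Y chromosome, had 778, 1098 and 1250 normalized counts in replicate 1 of Ascl5WT/WT, Ascl5Mut/Mut and Ascl5Mut/WT and was listed at 0 in every replicate 2. Tsix, which overlaps Xist on the opposite strand, had 126014, 310649 and 259527 in the replicates 2 and was listed at 0 in the replicates 1. Each genotype held 1 library of each kind.

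Of the 50 features with the highest mean, 29 had at least 500 bases opposite coding exons, and the 961 such features, 3.9% of those annotated, held 24.5% to 34.6% of the total per library. Among antisense RNA genes that overlap a coding gene by at least 200 bases, with a mean of at least 1000 summed over each pair, 80.0% (76 of 95, 95% Clopper-Pearson interval 70.5% to 87.5%) had a higher value per kb than the coding gene, which is consistent with reads assigned to the strand opposite their transcript. The test on ribosomal protein genes met the prediction written for it, with a median per kb 5.98 times higher opposite them, but only 3 of 6 such features exceeded their own gene, a condition added afterwards, so it was not counted as deciding. A median log2 ratio of Tsix to Xist per kb of 6.38 in the 3 libraries with Tsix also goes with reads assigned to the opposite strand. It argues against reads from both strands alike. Xist had 3060, 322 and 1411 normalized counts in the replicates 1, where Tsix was at 0, so a smaller share of reads from both strands is not excluded. If strands were exchanged, values given here for Gpr39, Gm11532, Copg2, Dlx1 and Shh may belong to Lypd1, Sp6, Mest, Dlx1as and 9530036O11Rik. Those of Masp2, Slc24a5 and Dst may belong to Tardbp, Myef2 and Gm26788, and those of Numb, Tnc and Gm10389 to Gm46367, 8030451A03Rik and Rai14. Further named genes with such an overlap are not listed, and genes without an overlapping partner would be undercounted. Dlx1as was lower in Ascl5Mut/Mut too, with 3897 and 1241 against 27823 and 10656 in Ascl5WT/WT.

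The lists higher in Ascl5Mut/Mut include tissues that surround a tooth germ. Reads of overlapping genes are argued against, since 6 of the 6 called lists passed again with only genes that have no opposite-strand overlap. On depth, all 5 lists called higher had more estimated reads in both Ascl5Mut/Mut libraries than in either Ascl5WT/WT library, by at least 1.36 times. The Ascl5Mut/Mut libraries were the shallower ones, so deeper sequencing of them did not make these sums. The lists were chosen for higher values and the steps differ little. This could therefore hardly come out otherwise and says no more about depth. More surrounding tissue in these samples may account for the pattern and stays open: of 10 lists of other cell types, leaving out those called higher, 8 had a median above 0 (exact one-sided sign test p = 0.055), and with genes at 0 set to the floor 3 were above 0, 6 were at 0 and 1 below (p = 0.31), and general epithelium was called lower without Ascl5Mut/Mut replicate 2 (camera adjusted p = 0.0133). The sign tests treat lists as independent, though all share the same libraries. An effect of the genotype on these tissues was not tested and stays open too. With 2 samples per genotype, dissection and genotype cannot be told apart.

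Dspp was higher in Ascl5Mut/WT and near the floor in the other genotypes. The test of bone tissue written before its result was seen did not decide, as Ibsp, Spp1 and Bglap together were 1.7 and 0.92 times Dspp in the 2 libraries. The lowest ratio of Dspp to these genes in Ascl5Mut/WT was 0.6. It was 12 times 0.05, the highest limit that the floor allows in the 3 other libraries with at least 20 bone reads. Those 3 libraries held bone reads without Dspp reads. Dspp had already been seen at 0 there, so the test could hardly come out otherwise and does not exclude more bone tissue. Ascl5WT/WT replicate 1 held only 3 reads of bone genes and 3 of Dspp, a ratio of 0.99. It was left out by the minimum of 20 reads, which was set after the values were seen. A later tooth stage in these samples may account for the higher Dspp. The enamel matrix and ameloblast list gave a camera p of 0.18 with a median of 3.50, which was 0 with genes at 0 set to the floor. This does not decide. A biological effect of 1 mutant allele was not tested apart from these.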
